A study of Mus musculus with 2 samples.

How the data were processed

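H3K9me3 ChIP-seq libraries were made from facial prominences of mouse embryos (strain B6NCrl, 12.5 days, mixed sex), with fragments of 300 to 500 bp selected, per the labels. The labels give 1 group with 2 biological replicates, pools of 120 and 88 embryos. The replicate numbers are those in the labels. No contrast between groups exists, so no test between groups of samples was made, and an SD is over the 2 replicates unless it is given as an SD over rotations.

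The analysis began from peak lists. Each replicate's list was derived from its alignments and 1 further file whose content is not stated, per the deposited descriptions that accompany the peak lists. The pooled list was derived from the alignments of both replicates and both of these further files, and the replicated list was derived from the pooled list and the 2 replicate lists, per the same deposited descriptions. The peak caller, its version, its threshold, the aligner and the rule for a replicated peak are not given in the sources used here. Each deposited peak has a signal value, which is the authors' own enrichment value and was used only to rank or filter peaks within 1 list. Each deposited peak also has −log10 p and −log10 q values from the authors' caller, and the lowest −log10 p values were 2.02 in the replicate 1 list and 2.05 in the replicate 2 list after rounding. Tested on the lists, all 16007 replicated peaks had the coordinates of a pooled peak, and every pooled peak that overlapped a peak of each replicate by at least 50% of either peak was in the replicated list. No read counts or coverage tracks were used, so the depth of each library and the precision it gives are unknown, and a region without a peak cannot be told from a region with too few reads. How reads with several matching positions were treated is not given either, which limits what can be said of repeated sequence.

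Coordinates are those of mm10 (GRCm38), per the labels. No peak reached beyond a chromosome end of the GRCm38 reference or lay wholly in a gap. Coordinates are printed counting from 1. Tests used chromosomes 1 to 19, X and Y, and peaks on the 44 unplaced or unlocalised scaffolds were left out of them. Gene models were those of GENCODE mouse release 21, and 21911 protein-coding gene symbols were tested. Of these, 14.0% carried a replicated peak within the gene span plus 2 kb on either side.

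Overlap between the replicates counted peaks with at least 50% of their length covered by the other list. The null was 1000 rotations of the other list along the known bases of each chromosome, which keep peak lengths and spacing. The same rotations of the replicated peaks served for annotation classes, in which a midpoint took the first of promoter, coding exon, 3' UTR, 5' UTR, other exon, intron and intergenic that held it. For GC content, CpG ratio and soft-masked share 200 rotations were drawn. For chromosome density, 1000 random draws over the known bases were made. For gene lists, the number of members with a replicated peak was set against the number expected from the share of hit genes in each of 10 groups of gene length. Membership was then rotated 10000 times along the gene order, which keeps gene clusters together. For zinc finger genes, peak bases were rotated 1000 times within each gene model, taken from the coding transcript with the longest coding sequence. All tests were two-sided permutation tests, with Benjamini-Hochberg adjustment over the 22 lists, the 7 annotation classes, the 21 chromosomes or the 4 gene parts. The smallest p is 1e-04 from 10000 rotations, 0.001 from 1000 and 0.005 from 200.

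The gene lists and the rule for named genes were fixed before the data were examined. Named genes were the 10 protein-coding genes with the most bases covered by replicated peaks and, of each list, the 4 members with the most covered bases, or all hit members where 5 or fewer were hit. The genes at or nearest to the 10 peaks with the highest signal were added, as were the 3 genes with the most covered bases in each of the 5 densest 1 Mb windows. Where a named gene had no peak in a replicate, this is stated. Covered bases are given as the mean ± SD of the 2 replicate lists over the gene span plus 2 kb. Members in several lists count in each.

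How often sequence recurs was measured with 31-base words counted over the whole reference on both strands. A peak was called single-copy where at least 90% of its words occur once. Random windows of 500 bp, 1000 per chromosome, served as a background. Alternatives set before the data were examined covered other overlap rules, stricter thresholds, each replicate's list alone, the pooled list, other gene spans, other nulls and other window sizes. Alternatives added later used only peaks found in each replicate, only single-copy peaks, noncoding genes, strata of length and GC content, and another definition of zinc finger genes.

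The tests were tested on simulated data. For gene lists, hits rotated along the gene order gave a p under 0.05 in 5.59% of 2200 tests. The test itself rotates membership along the same order, so a rate near this one follows from the design. It therefore cannot show how often the test calls unrelated lists in the data. The same lists were tested under repeated rotations, so these tests are not independent. A planted ratio of 3 in the zinc finger list was recovered as a median of 2.81 and called in 100 of 100 simulations. A planted ratio of 3 in the germline list was recovered as 3.01 and called in 99 of 100. For replicate overlap, a planted share of 30% among 42517 peaks was recovered as 29.8%. For the last exon, a planted share of 58.7% in 422 genes was recovered as 57.3%. Peaks placed at random within zinc finger genes gave a p under 0.05 for the last exon in 17 of 200 simulated sets, where 10 were expected, so this test may call too often. These simulated peaks had a single length and could not cross the ends of a gene, so they do not show how often it does so in the data. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and numba 0.67.0.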

Results

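H3K9me3, the trimethylated form of lysine 9 of histone H3 and a mark of silenced chromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic facial prominences at 12.5 days of development. The facial prominences are the swellings of neural crest mesenchyme, covered by surface epithelium, that grow together to form the face. The tissue came from the B6NCrl strain and held embryos of both sexes. There was 1 group with 2 biological replicates, a pool of 120 embryos for replicate 1 and a pool of 88 embryos for replicate 2. The labels name no treatment or second tissue, so the comparisons are between the replicates, and between the peaks and the rest of the genome. Replicate 1 had 42828 peaks with a median length of 251 bp, and replicate 2 had 41723 peaks with a median length of 226 bp. On the assembled chromosomes these peaks covered 13.1 Mb in replicate 1 and 11.2 Mb in replicate 2. The authors' list of replicated peaks held 16007 of the 56108 peaks called on the pooled replicates, with a median length of 415 bp. The 15773 replicated peaks on chromosomes 1 to 19, X and Y covered 8.06 Mb, or 0.304% of the known bases, and form the main peak set. Read counts were not used here, so the depth of each library is unknown.

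The first question was how far the 2 replicates marked the same places. Of the replicate 1 peaks, 18% (7639 of 42517) had at least 50% of their length covered by replicate 2 peaks, against a mean of 0.480% when the replicate 2 peaks were rotated along the chromosomes. Of the replicate 2 peaks, 21.3% (8824 of 41366) were covered by replicate 1 peaks, against 0.594% after rotation. Both shares lay above all 1000 rotations (two-sided permutation test, p = 0.001, the smallest these rotations can give). The shared peaks were concentrated among those with a high signal value. With each list ranked by signal and divided into 10 equal groups, 41.6% of the replicate 1 peaks and 48.2% of the replicate 2 peaks in the highest group were shared. The shares were lowest in group 8, at 9.97% and 12.4%, and were 15.4% and 15.0% in group 10. The shares of the whole lists depended on the overlap rule. With at least 90% of the peak covered they were 5.5% (replicate 1) and 9.79% (replicate 2). With any overlap of 1 bp they were 26.6% and 28.2%. A q of at most 0.05 was reached by 24094 of 42828 replicate 1 peaks and 18376 of 41723 replicate 2 peaks. With both lists cut to a −log10 q of at least 2 the shares were 14.1% (1763 of 12529) and 30.3% (2025 of 6686). Each share depends on the length of the other list, so these shares do not compare directly with those of the whole lists. Over 2737 windows of 1 Mb, the bases covered in the replicates rose together, with Pearson's r = 0.979 and Spearman's rho = 0.898 across windows, which are not independent replicates. Of the replicated peaks, 10824 overlapped a peak of each replicate by at least 50% of either peak. The remaining 32.4% overlapped a peak of 1 replicate only (4968) or of neither (215), and the rule that kept them is not given in the sources used here.

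**Figure D1:**
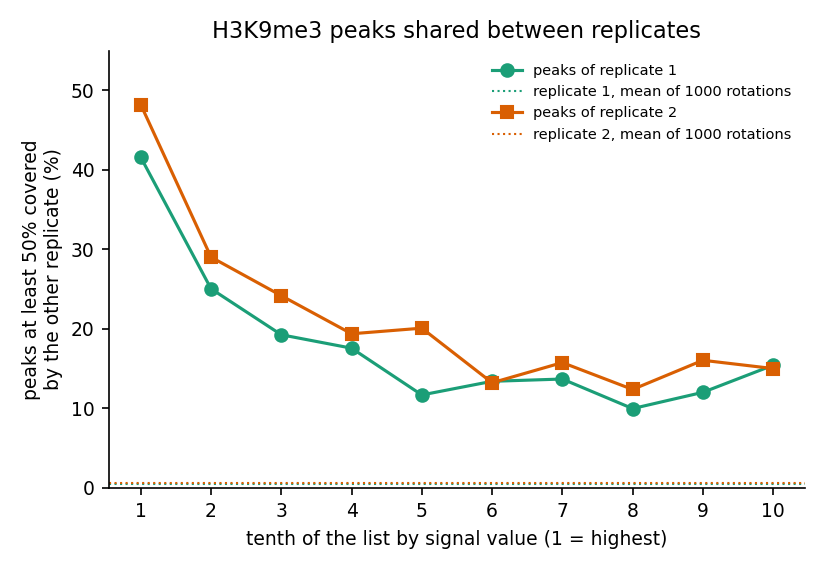
Share of each replicate's peaks (y axis, %) with at least 50% of their length covered by the other replicate, by group of the list ranked on the authors' signal value and divided into 10 equal groups (x axis, 1 is the highest). Circles are replicate 1, squares are replicate 2, and dotted lines are the means of 1000 rotations (0.480% and 0.594%); the highest group reached 41.6% and 48.2%.

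Of all 1 Mb windows of the assembled chromosomes, the one with the most bases in replicated H3K9me3 peaks lay over the clustered protocadherin genes, which encode cell adhesion proteins that give neurons their surface identity. The 1 Mb window of chromosome 18 from 37000001 to 38000000 (GRCm38) held 215 replicated peaks over 171077 bases, and the replicates covered 151772 ± 14085 bases of it (SD, n = 2). Replicated peaks lay within 2 kb of 52 of the 56 clustered protocadherin genes, where 13.8 were expected from the lengths of these genes. The ratio was 3.77, with an adjusted p of 0.0029 in the permutation test by gene order. In the replicates' own lists, where 25.4 and 26.2 were expected, 55 and 53 were hit, which lowered the ratio to 2.16 and 2.02. All 22 Pcdhb genes, 18 of 21 Pcdhg genes and 12 of 13 Pcdha genes were hit. Within 1 kb of a transcription start site, 41 of the 56 genes carried a peak, where 0.885 were expected. Pcdhga1 (chromosome 18, 37661793 to 37841873) had the most bases of the listed members, 74573 ± 1204 in the replicates (SD, n = 2). Pcdhga2 had 72309 ± 1621 bases, Pcdhga3 had 69216 ± 1581 and Pcdhgb1 had 64998 ± 1671. The 4 members with no replicated peak were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, which were named after their values were seen. The Pcdhg genes overlap and end together, so members share peaks, and the 56 genes make up 14 separate stretches, all of which were hit, by 176 distinct peaks. The predicted transcripts Gm42416, Gm37013 and Gm37388, annotated across most of the cluster, had the most covered bases of all protein-coding genes. Gm42416 had 159168 ± 14530 bases in the replicates.

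**Figure D2:**
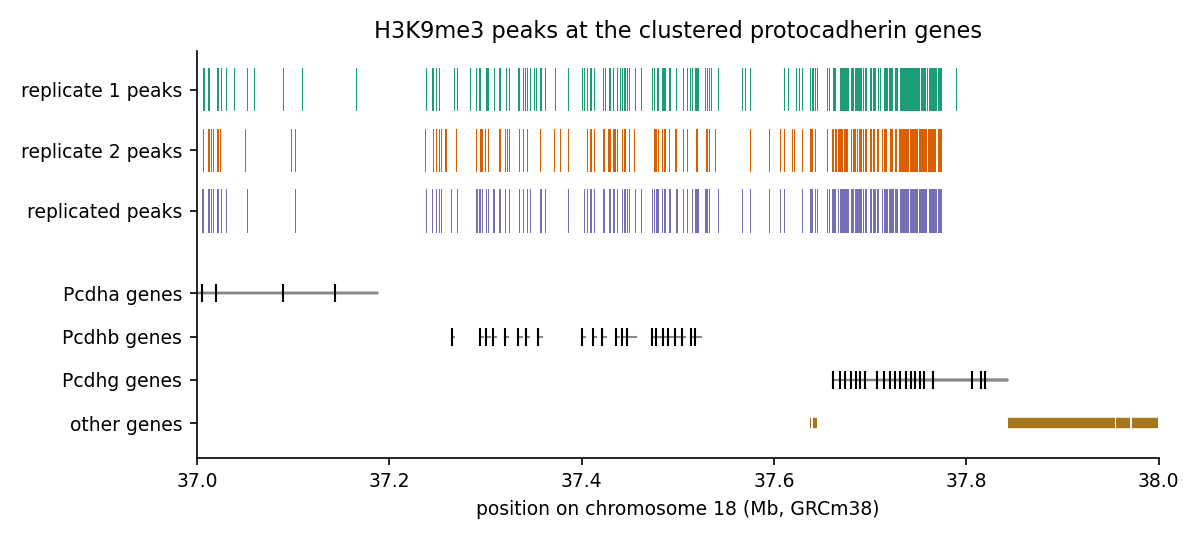
Peaks of replicate 1, of replicate 2 and of the replicated list (upper 3 tracks) and the genes below them, along chromosome 18 from 37 to 38 Mb (x axis, GRCm38). Black ticks mark the lower coordinate of each protocadherin gene and grey lines its span; the 215 replicated peaks crowd over the Pcdhb genes and the upstream exons of the Pcdhg genes.

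Zinc finger genes, many of which encode KRAB proteins that recruit silencing factors to repeated DNA, carried replicated peaks 3.11 times as often as genes of their length. Of 424 such genes, 158 were hit and 50.8 were expected (adjusted p = 0.0011, permutation test by gene order). In the replicates' own lists, 53.7% ± 3.5 of the members had a peak (SD, n = 2), but more genes of any kind were hit there. The ratio was 1.90 in replicate 1 (114.4 expected) and 2.09 in replicate 2 (113.8 expected), each with an adjusted p of 0.0011 (permutation test). Zfp873 on chromosome 10 (82048123 to 82064745) had 13848 ± 1699.9 covered bases, and Zfp936 on chromosome 7 (43114229 to 43192109) had 14669 ± 987. Zfp981 on chromosome 4 (146502027 to 146539395) had 11055 ± 2029 and Zfp110 on chromosome 7 (12834761 to 12850577) had 11662 ± 549. The window of chromosome 7 from 12000001 to 13000000, which holds Zfp110, Zfp606 and Zfp329, was among the 5 windows with the most covered bases on the assembled chromosomes. Within 1 kb of a start site, 11 of the 424 genes had a replicated peak, where 5.25 were expected, and with that narrower span the list did not pass the test (adjusted p = 0.21, permutation test).

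Within zinc finger genes, the peaks favoured the last exon, which in KRAB zinc finger genes encodes the array of fingers. In the 145 genes with peak bases inside the gene model, 42.7% of these bases lay in the last exon, against 18.3% ± 1.8 (SD over 1000 rotations) when the peaks were rotated within each gene. Introns held 54.0% against 78.4%, and first exons held 0.251% against 1.09%. The adjusted p was 0.0013 for each of these 3 parts (permutation test, raw p = 0.001, the smallest these rotations can give). In simulated sets with peaks placed at random the last exon's p fell under 0.05 in 17 of 200 cases, where 10 were expected, so these p values may be too small. The simulated peaks all had a single length and, unlike rotated ones, could not cross the ends of a gene. How far the p values of the data are off is therefore unknown. Internal exons held 3.02% against 2.28%, which did not pass (adjusted p = 0.057, permutation test). The share of the last exon was 39.5% in the replicate 1 list and 38.9% in the replicate 2 list. Of the 145 genes, 109 had peak bases in the last exon, and single genes differed. In Zfp386 the last exon held 72.2% of the peak bases and 28.6% of the gene model, and in Zfp936 it held 36.5% and 19.3%. The Zfp936 model, of 14522 bases, held only 3271 of the 16266 replicated peak bases in that gene's span plus 2 kb. Its share therefore leaves out most of the peak bases of the gene. In Zfp873 the last exon held 18.7% and 15.3%, and in Zfp981, with 6.9% and 7.0%, it was not favoured. Replicated peaks covered 100% of the last exon in Zfp873 and Zfp146, 42.5% in Zfp936 and 31.4% in Zfp865. In 2356 other protein-coding genes with peak bases, the last exon held 4.63% of them, against 3.81% after rotation. That excess was smaller (ratio 1.21, against 2.34 in zinc finger genes) but also reached the smallest p (permutation test, p = 0.001). First exons of these other genes held more than rotation gave, 2.25% against 0.996% (permutation test, p = 0.001), unlike those of zinc finger genes.

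**Figure D3:**
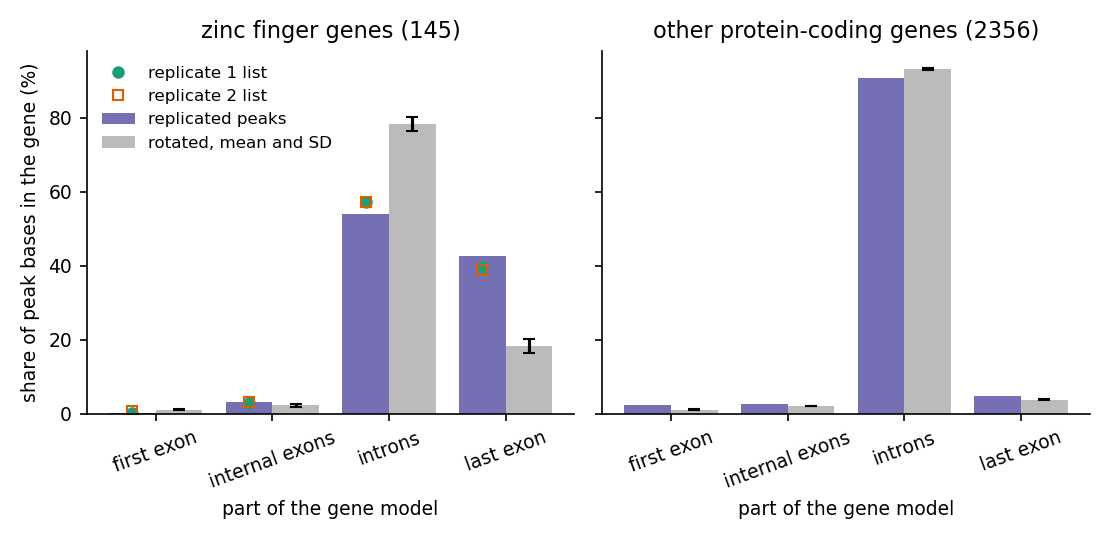
Share of replicated peak bases (y axis, %) in the first exon, internal exons, introns and last exon of gene models (x axis), in 145 zinc finger genes (left) and 2356 other protein-coding genes (right). Purple bars are replicated peaks, grey bars the mean and SD of 1000 rotations within each gene, and points the 2 replicate lists; the last exon of zinc finger genes held 42.7% against 18.3%.

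Imprinted genes, which are expressed from the maternal or the paternal copy alone, had the highest ratio of the 22 lists for replicated peaks within the gene span plus 2 kb. Of the 43 listed protein-coding genes 34 carried a replicated peak, where 8.07 were expected (ratio 4.21, adjusted p = 0.0011, permutation test). In the replicates' own lists 91.9% ± 1.6 of the members had a peak (SD, n = 2), with a ratio of 2.46 in replicate 1 and 2.33 in replicate 2. Neighbouring members can share a peak, and as separate stretches 27 of 35 were hit, by 74 distinct peaks. Gnas, the gene of the stimulatory G protein subunit (chromosome 2, 174284320 to 174346744), had 7549 ± 2053 covered bases. Mest on chromosome 6 (30723547 to 30748465) had 5082 ± 1135. Grb10, a growth factor receptor adaptor (chromosome 11, 11930508 to 12038683), had 5588 ± 467, and Blcap on chromosome 2 (157556362 to 157571274) had 3752 ± 358. Within 1 kb of a start site, 16 of the 43 genes carried a replicated peak, where 0.647 were expected (adjusted p = 0.0011, permutation test). Peg3 and Zim1 were members of both this list and the zinc finger list.

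Vomeronasal receptors, which detect pheromones, were hit in 89 of 328 genes, where 28.1 were expected (ratio 3.17, adjusted p = 0.0049, permutation test). The ratio was 1.83 in the replicate 1 list and 1.82 in the replicate 2 list (adjusted p = 0.019 and 0.014, permutation tests). The members with the most covered bases were Vmn2r60 (6911 ± 2725, SD, n = 2), Vmn2r16 (4625 ± 1151), Vmn1r73 (4462 ± 795) and Vmn2r53 (4697 ± 1490). With only the 1 kb around start sites this list did not pass the test either (9 genes, adjusted p = 0.34, permutation test). Olfactory receptors were hit in 100 of 1092 genes, where 66.3 were expected, which did not pass (adjusted p = 0.38, permutation test). Olfr398 had 2122 ± 984 covered bases, Olfr1349 had 2662 ± 705, Olfr365 had 1349 ± 419 and Olfr77 had 1435 ± 603.

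Germline genes, which serve meiosis and germ cells and are silent in body tissue, were hit in 15 of 59 cases, where 8.73 were expected (ratio 1.72, adjusted p = 0.063, permutation test). The list passed the test in each replicate's own peak list, with adjusted p = 0.0038 in replicate 1 and 0.019 in replicate 2 (permutation tests). It also passed when only the 1 kb around start sites counted, where 9 genes were hit and 0.807 were expected (adjusted p = 0.0011, permutation test). Dazl, a germ cell RNA-binding protein (chromosome 17, 50279395 to 50293636), had 1277 ± 285 covered bases (SD, n = 2) and a replicated peak of 1496 bases within 1 kb of a start site. Meioc had 1145 ± 386 bases, Taf7l had 809 ± 583 and Sycp1, a protein of the synaptonemal complex, had 528 ± 121. Cytochrome P450 genes, most of them liver enzymes, were hit in 21 of 93 cases, where 10.7 were expected (adjusted p = 0.063, permutation test). They too passed in each replicate's own list (adjusted p = 0.019 in replicate 1 and 0.012 in replicate 2, permutation tests). Cyp3a11 had 3831 ± 316 bases, Cyp2c29 had 3535 ± 132, Cyp3a16 had 3439 ± 475 and Cyp2b9 had 3146 ± 976.

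Genes that shape the face did not differ significantly from genes of their length. Of 71 craniofacial regulators 4 carried a replicated peak, where 9.07 were expected (ratio 0.44, adjusted p = 0.19, permutation test). In the replicates' own lists the ratio was 0.63 in replicate 1 (12 genes) and 0.93 in replicate 2 (18 genes). The 4 genes were Eya1 (602 ± 526 bases, SD, n = 2), Six4 (564 ± 441), Gli3 (1082 ± 878) and Col2a1 (845 ± 751). None of the 71 had a replicated peak within 1 kb of a start site. Few such peaks were expected in other lists of similar size, so their absence here does not show that these genes were avoided. Of 39 Hox genes 1 was hit, Hoxb3, where 2.52 were expected, and it had no peak in replicate 1. No replicated peak lay at any of 76 ribosomal protein genes, 68 histone genes, 53 keratin-associated protein genes or 26 kallikreins, where 3.94, 2.85, 2.06 and 1.45 were expected. In the replicates' own lists (replicate 1, then 2) the genes hit were 5 and 4 for Hox genes, 1 and 5 for ribosomal protein genes, 1 and 1 for histone genes and 3 and 3 for keratin-associated protein genes. Kallikreins differed between the replicates, with 9 of 26 genes hit in replicate 1 and 1 in replicate 2. None of these 5 lists passed the test (adjusted p from 0.38 to 0.66, permutation tests).

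The marker lists of other cell types also did not pass. Endothelial markers were hit in 1 of 16 genes (3.57 expected, adjusted p = 0.14, permutation test), which was Esam, with no peak in replicate 2. Hepatocyte markers were hit in 1 of 28 genes (Ambp, 2.78 expected), surface epithelium markers in 2 of 25 (Cdh3, and Krt8 with no peak in replicate 2, 3.29 expected) and muscle markers in 3 of 33 (Ttn, Ryr1 and Ckm, 3.95 expected). Blood and immune markers were hit in 3 of 36 genes (Cx3cr1, Runx1 and Pax5, 4.44 expected) and neuronal markers in 5 of 32 (Syt1, Snap25, Slc17a7, Nefm and Rbfox3, 4.20 expected). Defensins were hit in 6 of 64 genes, where 3.14 were expected, with the most bases at Defb33 (2123 ± 857, SD, n = 2). The other 3 defensins with the most bases were Defb39, Defb5 and Defb8. Rhox and related X-linked testis families were hit in 2 of 82 genes, where 6.06 were expected. These were Rhox13, and Magel2, which matched by symbol but lies on chromosome 7 and is also in the imprinted list. The expected number takes no account of chromosome, and X had 0.150 of the peak density under random placement. A low count in this list therefore cannot be told from the low density of X. Of 27 genes of the H3K9 methylation machinery 6 were hit, where 5.17 were expected. They included Smchd1 (892 ± 152), Fam208a (808 ± 374), Atf7ip (1287 ± 848) and the methyltransferase Setdb1, which had no peak in replicate 1. The adjusted p of these other lists ranged from 0.65 to 0.69 (permutation tests). The ratios depended on the list of peaks, and in the replicates' own lists none of these marker and family lists passed. Hepatocyte markers were hit in 7 genes in replicate 1 (ratio 1.10) and 2 in replicate 2 (0.31), and endothelial markers in 8 (1.16) and 4 (0.57). Surface epithelium markers were hit in 7 (1.03) and 6 (0.86), muscle markers in 10 and 10 (1.19 in each), and the Rhox and testis list in 5 (0.37) and 2 (0.15).

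**Figure D4:**
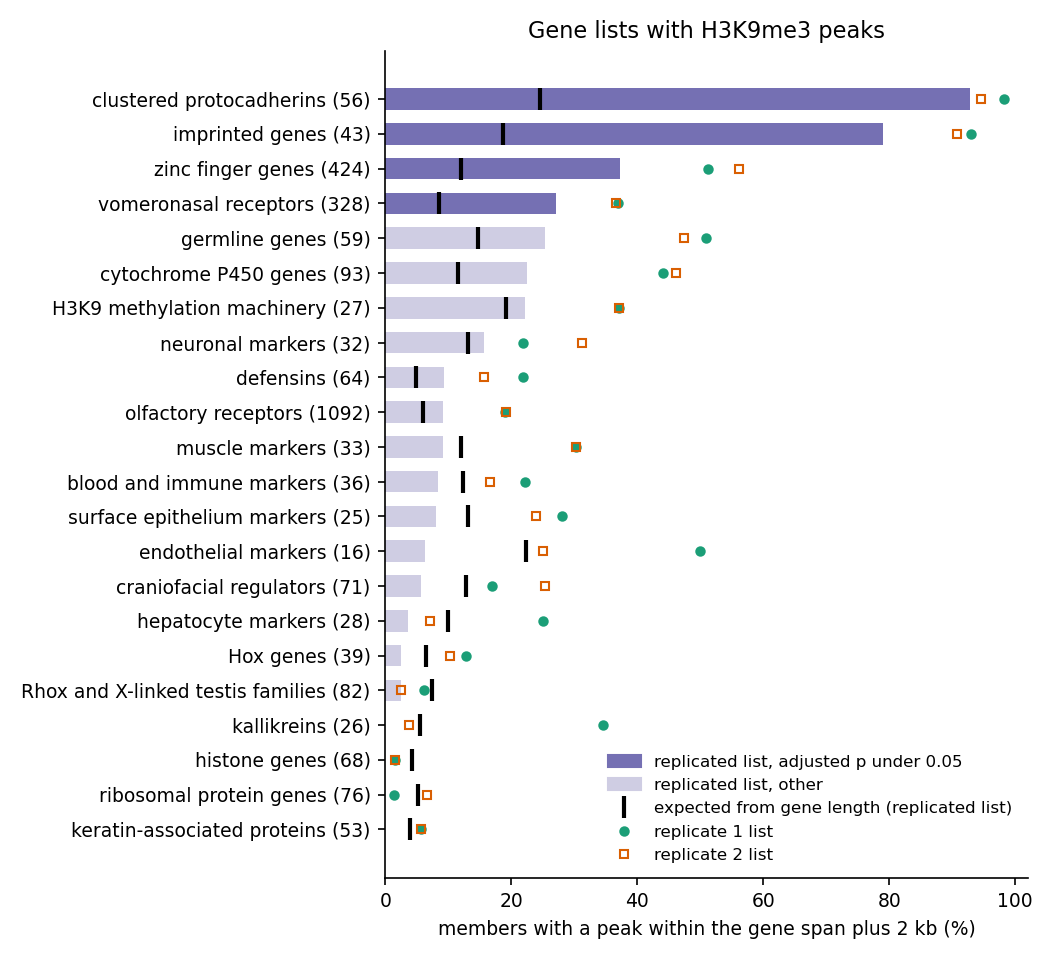
Share of members of each fixed gene list (y axis, number of genes in parentheses) with an H3K9me3 peak within the gene span plus 2 kb (x axis, %). Bars are the replicated list (dark where the adjusted p was under 0.05), black marks the share expected from gene length in that list, and points the 2 replicate lists; protocadherins (92.9%), imprinted genes (79.1%), zinc finger genes (37.3%) and vomeronasal receptors (27.1%) lay above their expectation.

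Of the 10 single peaks with the highest signal values, which are the authors' own, some lay in zinc finger and protocadherin genes and others outside all lists. The highest, 8.33, was at 30956281 to 30958901 on chromosome 6, with its midpoint in the 3' untranslated region of Klf14, a single-exon transcription factor gene. The next, 7.98, was at 5028719 to 5033021 on chromosome 7, with its midpoint in a coding exon, and overlapped Zfp865, Ccdc106 and Gm44973. Peaks in the protocadherin cluster had values of 7.63 and 6.69. A peak over Asmt, the gene of the last enzyme of melatonin synthesis, reached 7.5 on chromosome X (170674202 to 170678077). Its midpoint lay in an intron, and the peak ran past the upper end of the gene at 170678054. Peaks with midpoints in coding exons of Zfp386 (6.93) and Zfp146 (6.50) and in the promoter of Tcfl5 (6.81) followed. An intergenic peak of 6.72 near the start of chromosome 17 lay 100926 bp from Scaf8, and one of 6.54 on chromosome Y lay 465662 bp from Zfy1. Neither gene had a peak in either replicate. All 10 overlapped a peak of each replicate. The intergenic peaks on chromosomes 17 and Y were not single-copy, as fewer than 90% of their words occur once in the reference. The shares were 82.2% for the chromosome 17 peak and 39.4% for the chromosome Y peak, while the rest of the 10 reached 90%. Among the densest windows were 2 on chromosome 7 over Scgb1b24, Scgb2b26 and Scgb2b24, which encode secretoglobins (33000001 to 34000000), and over Ceacam5, Psg29 and Gm5155 (17000001 to 18000000). The replicates covered 80223 ± 19313 and 71169 ± 18997 bases of them (SD, n = 2). A window of chromosome 1 (88000001 to 89000000) held Mroh2a, with 32274 ± 446 covered bases, the ion channel gene Trpm8 with 21496 ± 1769.9 and Ugt1a7c, of the bilirubin-conjugating Ugt1a cluster, with 11904 ± 803.

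Per Mb of known sequence, chromosome 7 was the most densely marked chromosome and the sex chromosomes the least. Chromosome 7 held 2443 replicated peaks, 17.2 per Mb of known sequence, which was 2.89 times the density under random placement. Chromosome 17 followed with 11.6 per Mb and chromosome 4 with 8.75 per Mb. Chromosome X held 146 peaks, 0.893 per Mb, where the autosomes ranged from 3.39 to 17.2 per Mb. Chromosome Y held 8 peaks, 0.0908 per Mb, but only an estimated 4.43% of its sequence is single-copy. Per Mb of single-copy sequence Y had 2.05 peaks and X had 1.29, though none of the Y peaks was itself single-copy. Of the 21 chromosomes 8 were above and 10 below random placement (permutation test, adjusted p at most 0.0035). The calls above random placement for chromosomes 9 and 19 were lost in the upper 50% of peaks by signal, when bases were counted and, in a setting chosen after seeing the data, among peaks found in each replicate. Chromosome 12 passed above random placement in each replicate's own list and in the pooled list, and chromosome 8 in the replicate 2 and pooled lists. Random placement ignores the clustering of peaks, which makes these p values too small. In the replicates' own lists, chromosome X had 0.257 (replicate 1) and 0.230 (replicate 2) of the density under random placement, and chromosome 7 had 2.36 and 2.15 times that density.

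**Figure D5:**
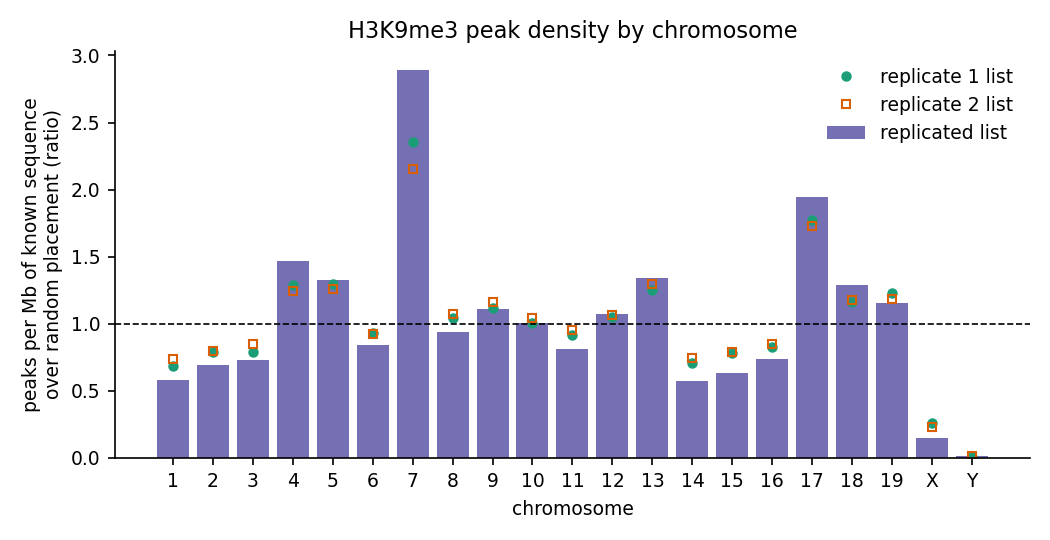
Peaks per Mb of known sequence on each chromosome (x axis), as a ratio to random placement over all chromosomes (y axis, dashed line at 1). Bars are the replicated list and points the 2 replicate lists; chromosome 7 stood at 2.89 and chromosome X at 0.150 in the replicated list.

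Against gene annotation, replicated peaks were more frequent in exons and promoters and less frequent in introns than rotated peaks. Promoters, the 1 kb either side of a start site, held 7.18% of peak midpoints against 4.81% after rotation. Coding exons held 2.54% against 1.26%, and exons of transcripts without coding sequence held 1.19% against 0.669%. Introns held 33.1% against 42.2%, each with an adjusted p of 0.0017 (permutation test). Intergenic sequence held 54.4% against 49.7% (adjusted p = 0.0042, permutation test), a call that was lost when bases were counted in place of midpoints. The 3' and 5' untranslated regions, with 1.5% and 0.0317%, did not differ from rotation (adjusted p = 0.11 and 1.0, permutation tests). Peaks had a higher GC content than rotated peaks, 47.0% against 42.1% (permutation test, p = 0.005, the smallest that 200 rotations can give). The ratio of observed to expected CpG was 0.195 against 0.194 (permutation test, p = 0.61). Peaks and random 500 bp windows were alike in how often at least 90% of their 31-base words occur once, 66.4% against 66.6%, and differed in highly repeated sequence. In 0.114% of replicated peaks the median 31-base word occurred 10 or more times in the genome, against 11.6% of random 500 bp windows. How reads with several matching positions were treated is not given. A lack of peaks in such sequence therefore cannot be told from a lack of usable reads.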

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

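Peaks on sequence outside the assembled chromosomes were left out of the comparisons, and they were numerous for the length of that sequence. The replicated list held 234 peaks on 23 of the 44 unplaced or unlocalised scaffolds, whose known bases add up to 5.25 Mb. That is 44.6 peaks per Mb, 7.49 times the 5.96 per Mb on the chromosomes. Of these, 59 lay on a single scaffold. The replicates' own lists held 311 (replicate 1) and 357 (replicate 2) peaks there, 59.3 and 68.1 per Mb, against 16.1 and 15.6 per Mb on the chromosomes. The ratio was thus lower in these lists, 3.69 and 4.36, and in the pooled list, 2.73. No control data were used, and no explanation of these peaks was tested.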

How the results depend on the processing

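The replicate overlap, the densities of chromosomes 7, X and Y and the last exon's share of zinc finger peak bases kept their direction and their side of the threshold under every alternative tried, as did the imprinted and protocadherin lists. Ratios over the alternatives ran from 2.32 to 24.7 for imprinted genes and from 2.02 to 46.3 for clustered protocadherins, both highest for 1 kb around start sites. With that span the zinc finger ratio was 2.10 and the vomeronasal ratio 1.77, and neither passed. The causes of the changes below were not tested. Counting gene bodies without flanks, 1 list fell below expectation (endothelial markers, 0 of 16 genes) where the main setting had none. The 3' UTR share passed at 1.70% in the upper 50% by signal, at 1.76% of bases and, in a setting chosen after seeing the data, at 1.59% for peaks found in each replicate. Counted in bases, the 5' UTR share passed at 0.0553% and the intergenic share, 51.8%, did not. Spearman's rho across windows was 0.833 with 500 kb windows, 0.712 at a −log10 q of at least 2 and 0.836 in the upper 50% by signal. The densest 5% of windows held 48.4% of covered bases, 32.7 to 36.4% with a replicate left out, 36.7% in the pooled list, 53.7% in the upper 50%, 51.4% for peaks found in each replicate and 52.1% with 500 kb windows. The CpG ratio passed below rotation without replicate 2 (0.186) and in the pooled list (0.182) and above it in the upper 50% (0.210), and did not pass without replicate 1 (0.190). The soft-masked share, whose masking source is not known, was 32.1% against 33.9% after rotation (permutation test, p = 0.025), and 33.2% in the pooled list, which did not pass. Depth is unknown and limits every statement on missing peaks. No paired analysis was possible because there is 1 group.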

Other observations

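Beyond the protein-coding members, noncoding RNAs of imprinted loci carried replicated peaks. Of 8 such RNAs in the fixed list 6 were hit, chosen for mention after their values were seen. Airn, the antisense RNA of Igf2r (chromosome 17, 12741311 to 12860136), had 5891 ± 1445 covered bases (SD, n = 2). Kcnq1ot1 on chromosome 7 had 4176 ± 1274, Nespas on chromosome 2 had 3977 ± 1099.6, Meg3 on chromosome 12 had 2804 ± 146, Peg13 on chromosome 15 had 2167 ± 865 and Rian had 1399 ± 771. H19 and Mirg had no replicated peak. With coding and noncoding members together, 40 of 51 imprinted genes were hit, where 8.93 were expected. These RNAs can share peaks with protein-coding members already counted. Nespas (174281237 to 174295436), for example, overlaps Gnas (174284320 to 174346744), so the hits are not all separate.

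Gene families outside the fixed lists were formed by symbol stem after the densest windows were seen. Of 250 families with at least 10 members none passed the permutation test by gene order after adjustment, while 11 were above and 14 below expectation at an unadjusted p under 0.05. The Nlrp genes came closest, with 9 of 17 members hit, where 2.81 were expected (adjusted p = 0.10, permutation test). In the replicates' own lists 79.4% ± 4.2 of Nlrp members were hit (SD, n = 2), against 29.6% (replicate 1) and 30.1% (replicate 2) of all genes tested. Phosphodiesterase genes (Pde) followed, with 14 of 26 members hit, where 8.01 were expected (adjusted p = 0.15, permutation test). Secretoglobin genes (Scgb) were hit in 11 of 34 members, where 1.45 were expected (p = 0.021, adjusted p = 0.45, permutation test). Ceacam genes were hit in 7 of 15, where 1.27 were expected, Sult genes in 9 of 21, where 2.63 were expected, and Ugt genes in 9 of 22, all 9 at the Ugt1a locus, where 4.34 were expected (adjusted p = 0.45 to 0.47, permutation tests). The families below expectation with the smallest p were Phf, hit in 0 of 22 members, where 4.18 were expected, and Nek, hit in 0 of 11, where 2.82 were expected (adjusted p = 0.45 for each, permutation tests). The replicates' own lists did not agree on them, with 36.4% of Phf and 27.3% of Nek members hit in replicate 1 and 13.6% and 63.6% in replicate 2.

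In the 3 patterns that follow, the settings tested were chosen after the main results were seen. Zinc finger genes carried replicated peaks more often than genes of their length, and 3 technical explanations were tested. If sequence shared with other copies were the cause, the ratio of hit to expected members would fall to 1.5 or below with single-copy peaks, and it was 3.11. Within 5 groups of length and 5 of GC content it was 3.00, and with only peaks found in each replicate it was 3.81 (adjusted p = 0.0011 for the first and last and 0.00073 for the strata, permutation tests). The tables therefore argue against each of these as the whole cause. A role of the mark at these genes in facial tissue remains a hypothesis, since no other tissue was analysed here to set it against.

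The last exon of zinc finger genes held more peak bases than rotation gave. If intron sequence shared with other copies kept peaks out of introns, the excess would fall to 1.5 or below when peaks and rotations were confined to single-copy bases, and it was 2.25 (44.2% against 19.6%). Windows were also matched in 5 groups of GC content, the highest from 49 to 76%. Set against intron windows of the same group, last exon windows were covered 6.39 times as much. Rotations already gave a mean of 1.84 and at most 2.56 (permutation test, p = 0.001, the smallest these rotations can give). These values argue against both as the whole cause. No biological explanation was tested.

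Chromosome X carried fewer replicated peaks per Mb than the autosomes. Per Mb of single-copy sequence, X had 0.187 of the autosomal median, where the lowest autosome had 0.589, and outside genes and promoters it had 0.147, where the lowest autosome had 0.624. Less single-copy sequence and fewer genes on X are thus unlikely to be the whole cause. A lower X dose in mixed-sex pools may lower X signal. Among called peaks the median signal was 2.94 on X and 3.05 on the autosomes. The 90th percentile of autosomal signal was reached by 17 X peaks (11.6%). Weak X peaks that were not called do not enter these values. With that percentile as the threshold, lowered to 0.75 times for X alone, X reached 0.899 of the autosomal median of peaks per Mb. That test cannot separate dose from another cause, since thinning X alike at every signal value would give 0.964, so dose stays open, and no biological explanation was tested.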
